A study of Homo sapiens with 108 samples.

How the data were processed

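Gene expression was measured in 4 non-Hodgkin lymphoma cell lines, WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer, on 108 Affymetrix arrays. Each line was treated with DMSO, with EPZ6438 at LCC or with EPZ6438 at 10xLCC, and RNA was taken at days 2, 4 and 6. The 36 groups held 3 arrays each, named replicates A, B and C in the labels. Groups were taken from the sample titles and characteristics. The concentration that LCC stands for in each line is not given in the sources used here, so doses are named as in the labels and are not comparable in concentration between lines.

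Per the labels' protocols, total RNA was purified with a silica column kit that included a DNase step, its integrity was measured by capillary electrophoresis, and it was copied to cDNA and transcribed into biotin-labelled antisense RNA in a single round. Per the submitters' processing notes the arrays were processed with GCRMA, whose version is not given in the sources used here. GCRMA subtracts background by probe sequence, normalizes arrays by quantiles and summarizes probes, so a change of the whole transcriptome would be largely removed. The deposited values of the arrays had similar but not identical distributions, with medians from 6.25 to 6.45 and upper quartiles from 7.68 to 8.28 (log2). The deposited values were intensities on a linear scale, from 5.79 to 31846, 1 per probe set and array. Every column of the deposited table matched 1 sample.

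The intensities were converted to log2 with a pseudocount of 0. The array's annotation named 1 gene for 41097 of the 54675 probe sets, several genes for 1801 and none for 11777, and only probe sets with 1 gene were used for named results. They stood for 19777 genes, of which 19735 matched a gene of the RefSeq annotation of GRCh38.p14, used for names and chromosomes; 0 symbols were updated. For the 10523 genes with several probe sets, the probe set with the highest mean over all arrays was used, and the text says where the others moved against it. A gene was tested in a line when its log2 value was at least 4 on at least 3 of the line's 27 arrays. Precision is limited by the number of arrays, 3 per group.

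For each line 1 linear model over its 9 groups was fitted with limma (lmFit and eBayes), and 9 contrasts were taken: LCC against DMSO and 10xLCC against DMSO at each of the 3 days, 10xLCC against LCC at day 6, the 10xLCC effect at day 6 minus that at day 2, and DMSO at day 6 against day 2. P-values were adjusted by Benjamini-Hochberg over the genes tested in a contrast, and a gene was called when its adjusted p was below 0.05. "Rose" and "fell" are used of called genes. Changes are log2 differences of group means with their standard errors (SE), and group values are means with SD (n = 3 arrays). A further model over all 108 arrays compared the day 6 10xLCC effect in Pfeiffer with the mean effect in the 3 lines that carry the EZH2 Y641 mutation. Tests are two-sided. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, so the adjusted p-values rest on limma's pooled estimate of the spread.

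Before the data were examined, 27 gene lists, the tests, the processing alternatives and the rule for named genes were fixed. The lists covered PRC2 and PRC1 subunits, CDK inhibitors, mitosis, DNA replication, ribosome biogenesis, cholesterol synthesis and uptake, germinal centre, plasma cell, and memory and activated B cell genes, B cell receptor signalling, MHC class I and antigen processing, MHC class II, the interferon response, NF-kB targets, pro-apoptotic, anti-apoptotic, p53 and glucocorticoid receptor target genes, the unfolded protein response, homeobox and developmental regulators, neuronal genes, MAPK feedback, integrins and cell adhesion, and T cell, myeloid, and epithelial and stromal markers. They were written from general knowledge, and some genes stand in several lists. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and adjusted over 27 lists in 4 lines, 108 tests. The test was repeated with the correlation estimated from the data.

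The named-gene rule took, for each line's day 6 10xLCC contrast, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose 3 treated arrays all lay on the same side of the 3 DMSO arrays, which chance gives for 10% of genes. It further took up to 12 genes each way called in all 4 lines, 8 each way for the comparison of Pfeiffer with the Y641 lines, 3 each way for the dose, time and DMSO contrasts, and up to 4 members of each list with the smallest p. EZH2, CDKN1A, CDKN2A, PRDM1, IRF4, BCL6, TXNIP, ABAT and TNFRSF21 were always included.

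The alternatives set beforehand were no filter on dim genes, a filter at log2 6, the mean of a gene's probe sets, centring of each array on the median of the genes with a log2 value of at least 8 on every array, limma with trend and robust variance estimates, the replicate letter as a block, a fit of the 2 groups compared alone, the estimated correlation for lists, and leaving out each array of a comparison in turn, or, for lists and shared genes, replicate A, B or C of every group. A fit without Pfeiffer LCC day 6 replicate B, a fit with the 3'/5' actin ratio as a covariate and a fit with array weights were chosen after seeing the data. The 3'/5' ratio is the log2 difference between the array's control probe sets at the 3' and 5' ends of beta-actin, and rises when RNA is degraded or incompletely copied. The fit and list code was tested on simulated data made from each gene's real mean and spread, with known changes added. In the day 6 10xLCC contrasts it recovered 59.7%, 58.2%, 46.3% and 32.8% of genes changed by 0.5 in WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer, and 100%, 98.5%, 95.5% and 88.1% of genes changed by 1. Only 67, 67 and 66 genes were changed, by 0.5, 1 and 2, and noise was drawn for each gene independently. Far more genes were called in the Y641 lines, so these shares do not carry over to them, and the simulated lists held no correlation between genes. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.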

Results

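RNA of 4 human non-Hodgkin lymphoma cell lines was profiled on 108 arrays after treatment with EPZ6438, an inhibitor of EZH2, the catalytic subunit of the PRC2 histone methyltransferase that represses genes. WSU-DLCL2, SU-DHL6 and Karpas422 carry the EZH2 Y641 mutation and Pfeiffer does not, per the series description. Each line had 9 groups of 3 arrays, DMSO, LCC and 10xLCC at days 2, 4 and 6, so 27 arrays per line and 36 groups in all. The labels name the replicates A, B and C without saying whether they were separate cultures, so the spread between them is read here as the spread of the experiment as labelled. The median distance of an array from the other replicates of its group was 0.170, 0.176, 0.171 and 0.169 (root mean square over genes, log2) in WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer. The highest distances were 0.317 for WSU-DLCL2 10xLCC day 6 replicate B, 0.474 for SU-DHL6 DMSO day 2 replicate A, 0.378 for Karpas422 LCC day 6 replicate C and 0.723 for Pfeiffer LCC day 6 replicate B. The number of arrays, 3 per group, limits the precision of every value. Chromosomes are those of GRCh38.p14, and changes are log2 differences from DMSO with their SE (n = 3 arrays per group) unless stated otherwise.

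The question of the main comparison, 10xLCC against DMSO at day 6, was which genes respond to EZH2 inhibition in each line. In WSU-DLCL2 the receptor genes CNR1 and LY75 were among the 10 largest rises, and the lists of DNA replication and mitosis fell. CNR1 on chromosome 6, the cannabinoid receptor, rose by 5.01 ± 0.16 (adjusted p = 9.4e-18), a 32.2-fold change from 4.47 ± 0.31 to 9.48 ± 0.10 (SD, n = 3). Its DMSO arrays lay higher at the earlier days, at 5.93 to 6.48 at day 2 and 7.60 to 7.95 at day 4. At 10xLCC they lay at 9.70 to 9.97 and 9.81 to 10.25, so the size of the day 6 change rests partly on a lower control. LY75, an endocytic receptor of antigen-presenting cells, rose by 4.83 ± 0.19, and AIG1, a lipid hydrolase, by 4.27 ± 0.14. JMY, ATXN1, DDAH1, SPINT2, KBTBD11, EFCAB12 and TRIM9 rose by 3.71 to 4.42. Among the falls, MCM10, a replication initiation factor on chromosome 10, changed by −2.85 ± 0.11 (adjusted p = 3.2e-16), and CDC6, which loads the replicative helicase, by −2.40 ± 0.12. PIR, a nuclear iron-binding protein, changed by −2.90 ± 0.18, and BCL2A1, an inhibitor of apoptosis, by −2.88 ± 0.15. RGS16, CHEK1, SLC7A11, LINC00158, SPC25 and ATAD2 changed by −2.77 to −2.23. Of 18843 genes tested, limma called 6808, of which 3199 rose and 3609 fell, and 687 rose and 470 fell at least 2-fold. With each array centred on bright genes the median change of all genes moved from 0.02 to 0.15, and the split moved to 4790 risen and 2757 fallen of 7547.

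In SU-DHL6 the largest rises included FCRL4, CCR7 and SATB1, and the largest falls included the checkpoint genes CHEK1 and MAD2L1. TMEM200A on chromosome 6 rose by 5.60 ± 0.19 (adjusted p = 3.3e-17), a 48.5-fold change. FCRL4, an inhibitory Fc receptor-like protein of B cells, rose by 5.53 ± 0.15, SATB1, a nuclear organizer of lymphocyte chromatin on chromosome 3, by 4.44 ± 0.11, and CCR7, a lymph node homing receptor, by 4.20 ± 0.21. RAPGEF2, TAPT1-AS1, IL18R1, RAI1, ABAT and SESN3 rose by 3.78 to 4.34. For RAI1 only 1 of 3 probe sets moved that way. Among the falls, CHEK1, the DNA damage checkpoint kinase on chromosome 11, changed by −2.69 ± 0.13, DLGAP5, a spindle protein, by −2.45 ± 0.17, and MAD2L1, of the spindle checkpoint, by −2.45 ± 0.19. MNS1, GNPDA1, EIF4E, PBK, LAT2 and RLIG1 changed by −2.71 to −2.10. For LAT2 1 of 2 probe sets moved that way. Limma called 8785 of 18896 genes, of which 3734 rose and 5051 fell, and 977 rose and 644 fell at least 2-fold. The log2 ratio of the 3' to the 5' end of beta-actin on the array, which rises with degraded RNA, was 0.34 ± 0.134 (SD, n = 3) at 10xLCC and −0.18 ± 0.026 in DMSO at day 6. At day 4 it was −0.05 and −0.12. With this ratio as a covariate, an alternative chosen after seeing the data, 1675 genes were called, 1124 risen and 551 fallen. Among the 20 genes with the largest changes only the call of HINT3 (−2.26 ± 0.19) ended, at −0.95 (adjusted p = 0.058), and as the mean of its 3 probe sets it was −0.16 (adjusted p = 0.38). Centring moved the median change of all genes from −0.11 to −0.01 and the split to 4634 risen and 3567 fallen of 8201.

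In Karpas422 the largest rises included CNR1, CXCR4 and ID2, the interferon response list rose, and the largest falls included replication genes and the cytokine genes TNF and LTA. CNR1 rose by 6.08 ± 0.10 (adjusted p = 4.5e-24), a 67.6-fold change, and CXCR4, the chemokine receptor on chromosome 2, by 5.73 ± 0.14. TAGAP, a GTPase-activating protein of lymphocytes, rose by 5.24 ± 0.15, and ID2, an inhibitor of helix-loop-helix transcription factors, by 4.55 ± 0.11. Further rises were IFI27, an interferon-induced gene, by 4.46 ± 0.26, and PMAIP1, a pro-apoptotic BH3-only protein, by 4.27 ± 0.15. H2AC6, HEPACAM2, KLHL14 and AFF1 rose by 4.16 to 4.57. Among the falls, the cytokine genes TNF and LTA on chromosome 6 changed by −2.63 ± 0.12 (adjusted p = 2.1e-15) and −2.38 ± 0.13, and the replication genes MCM10 and MCM4 by −2.75 ± 0.15 and −2.71 ± 0.17. CHEK1, LMNB1, ANKLE1, TRIP13, GINS4 and SMG1P5 changed by −2.92 to −2.41. Limma called 7093 of 18874 genes, of which 3464 rose and 3629 fell, and 877 rose and 804 fell at least 2-fold. The 3'/5' log2 ratio was high in every group at day 6, 1.25 ± 0.221 (SD, n = 3) in DMSO and 2.25 ± 0.509 at 10xLCC, against −0.01 and 0.03 at day 4. Centring moved the median change of all genes from −0.03 to 0.13 and the split to 5023 risen and 2674 fallen of 7697.

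In Pfeiffer fewer genes passed the test, and the changes were smaller. RCSD1, an actin capping regulator on chromosome 1, rose by 1.75 ± 0.13 (adjusted p = 4.6e-09), from 6.34 ± 0.15 to 8.10 ± 0.22 (SD, n = 3). TP53INP1, a p53-induced autophagy protein on chromosome 8, rose by 1.28 ± 0.14, P4HA2, a collagen prolyl hydroxylase, by 1.20 ± 0.16, and TRIB1, a pseudokinase, and LINC01943 by 1.17 each. PNMA8A fell, by −0.92 ± 0.15 (adjusted p = 0.0047). Limma called 42 of 18936 genes, of which 31 rose and 11 fell, and 8 rose and 0 fell at least 2-fold. Among the 20 genes with the largest changes 5 calls ended as the mean of probe sets and 5 in the fit of the 2 groups alone. With the 3'/5' covariate 2 of these calls ended, and 17 of the 20 genes were bright enough for the stricter filter. Centring gave 458 genes (320 risen and 138 fallen) and the fit of the 2 groups alone 90 (74 and 16). Of all genes tested 923 had an unadjusted p under 0.05, no more than chance alone gives at that threshold. The pooled spread behind these p-values included LCC day 6 replicate B, so the count does not show that other genes stayed unchanged. The call of TNFRSF21, a death receptor that rose by 3.85 ± 0.19 in Karpas422 (here 1.28 ± 0.23), ended without DMSO replicate B (adjusted p = 0.076) or C (0.083) and without 10xLCC replicate B (0.084) or C (0.061). CNR1, at 1.14 ± 0.21, was not called without DMSO replicate A (0.063) or B (0.11) or 10xLCC replicate B (0.064) or C (0.11). Leaving out single arrays of the comparison gave 12 to 33 genes, with 12 without DMSO replicate A, 20 and 27 without DMSO replicates B and C, and 16 and 21 without 10xLCC replicates B and C. Without Pfeiffer LCC day 6 replicate B, which stood apart from its group, 450 genes were called, 340 risen and 110 fallen, among them all 42. This alternative was chosen after seeing the data.

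**Figure D1:**
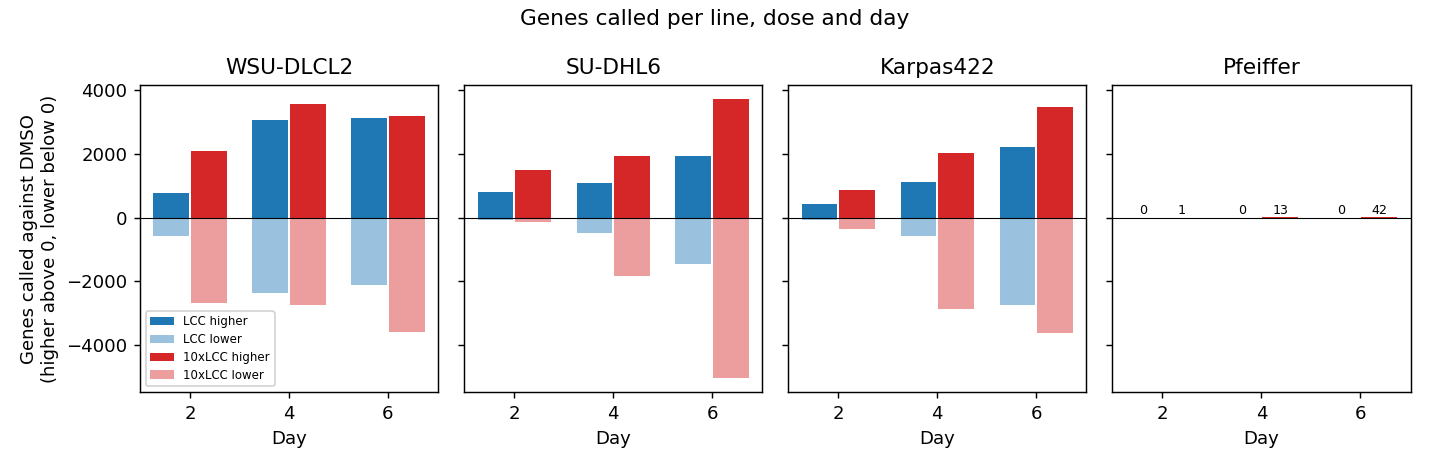
Genes called by limma (vertical axis, number of genes, higher above 0 and lower below it) for LCC and 10xLCC against DMSO at days 2, 4 and 6 in each line. At day 6 and 10xLCC the counts were 6808, 8785, 7093 and 42 in WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer.

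The cell cycle lists moved together in the 3 Y641 lines. Of 31 DNA replication genes, which copy the genome, 31 fell in WSU-DLCL2, 29 in SU-DHL6 and 31 in Karpas422. CDC45 changed by −1.95 ± 0.08, −1.27 ± 0.10 and −2.17 ± 0.09, and RRM2, a subunit of the enzyme that makes deoxynucleotides, by −1.80 ± 0.07, −1.23 ± 0.09 and −2.28 ± 0.15. The list test gave adjusted p = 3.8e-33, 3.4e-15 and 2.3e-29, and adjusted p = 0.0156, 0.151 and 0.0156 with an estimated correlation. Of 30 mitosis genes 30, 26 and 30 fell. CCNA2, a cyclin, changed by −1.53 ± 0.12, −1.45 ± 0.10 and −1.52 ± 0.12, and the spindle protein ASPM by −1.30 ± 0.10, −0.76 ± 0.08 and −2.24 ± 0.11. Its test gave adjusted p = 2.3e-29, 1.7e-11 and 5.6e-27, and with an estimated correlation adjusted p = 0.0288, 0.194 and 0.0242. Of 22 ribosome biogenesis genes 18, 18 and 22 fell, with MRTO4 at −0.85 ± 0.08, −1.02 ± 0.09 and −1.38 ± 0.10. In WSU-DLCL2 the direction was the opposite at day 4, when 13 rose and 0 fell at 10xLCC (median 0.32) and 10 and 0 at LCC, after 0 and 11 at day 2 with 10xLCC. The control moved as well, since 13 of these genes rose and 0 fell in WSU-DLCL2 DMSO from day 2 to day 6 (median 0.31). The day 6 fall there (median −0.38) thus rests partly on a higher control. The day 6 list test gave adjusted p = 5.1e-07, 1.4e-05 and 6.0e-15, and adjusted p = 0.263, 0.399 and 0.0271 with an estimated correlation. In Pfeiffer 0 members of these lists passed limma's test alone, and 923 of all genes had an unadjusted p under 0.05. That is no more than chance gives, but Pfeiffer's pooled spread included LCC day 6 replicate B. The count therefore does not show that these genes stayed unchanged. Medians in Pfeiffer were −0.13 for both DNA replication and mitosis (adjusted p = 5.3e-09 and 8.8e-10, and adjusted p = 0.435 and 0.416 with an estimated correlation). Its ribosome biogenesis list was not called (adjusted p = 0.662). The list falls in SU-DHL6 and Karpas422 stood beside the raised day 6 3'/5' ratios of 0.34 and 2.25.

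Of 14 MHC class II genes, which present antigen to T cells, 14 rose in WSU-DLCL2, 14 in SU-DHL6 and 7 in Karpas422, where 1 fell. HLA-DOB, a modulator of peptide loading, rose by 0.89 ± 0.08, 1.95 ± 0.08 and 1.42 ± 0.08, and HLA-DOA, its partner, by 1.59 ± 0.07, 1.83 ± 0.08 and 1.18 ± 0.10. Of the 5 HLA-DOA probe sets 4, 2 and 3 moved that way, and of the 2 HLA-DOB probe sets 1 did in Karpas422. The test gave adjusted p = 1.6e-13, 6.9e-12 and 0.0046, and with an estimated correlation adjusted p = 0.0334, 0.0306 and 0.399. In Pfeiffer the list's median was 0.27 (adjusted p = 5.3e-09; adjusted p = 0.235 with an estimated correlation), with 0 members called over all genes, 7 risen without LCC day 6 replicate B and 8 risen when adjusted over the list alone. Of 17 genes of MHC class I and antigen processing 8 rose and 2 fell in WSU-DLCL2, 9 and 3 in SU-DHL6, 10 and 2 in Karpas422 and 0 in Pfeiffer, where 2 were called adjusted over the list alone. HLA-B rose by 1.41 ± 0.08, 1.23 ± 0.07 and 1.67 ± 0.12, and TAP1, the peptide transporter, rose in SU-DHL6 (1.47 ± 0.10) and Karpas422 (0.90 ± 0.10) and fell in WSU-DLCL2 (−0.51 ± 0.09). That list was not called in WSU-DLCL2 (adjusted p = 0.0639, but 0.022 without replicate B and 0.049 with trend and robust estimates). It was called upward in SU-DHL6 (0.0126, but 0.0587 without replicate B), Karpas422 (1.7e-05) and Pfeiffer (3.5e-04). Each call was lost with an estimated correlation (adjusted p = 0.535, 0.206 and 0.533).

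Of the B cell lists, those of receptor signalling and of the germinal centre were called upward in the 3 Y641 lines at the preset correlation. Of 19 B cell receptor signalling genes 16 rose and 2 fell in WSU-DLCL2, 13 rose in SU-DHL6, 14 rose and 3 fell in Karpas422, and 1 fell in Pfeiffer. PRKCB, the protein kinase C beta that signals to NF-kB, rose by 3.38 ± 0.10, 1.23 ± 0.10 and 2.44 ± 0.12. Its fall in Pfeiffer, −0.65 ± 0.11, was no longer called without DMSO day 6 replicate A (adjusted p = 0.051) or as the mean of its probe sets (−0.18, adjusted p = 0.90). The list test gave adjusted p = 7.1e-06, 4.2e-07, 9.4e-05 and 0.765, and the calls were lost with an estimated correlation (adjusted p = 0.249, 0.193 and 0.193). Of 17 germinal centre genes 10 rose in each Y641 line and 2, 1 and 1 fell, with BACH2, a repressor of plasma cell differentiation, at 2.32 ± 0.10, 1.75 ± 0.12 and 3.67 ± 0.10. The germinal centre test gave adjusted p = 0.0021, 2.9e-04 and 2.5e-04 (adjusted p = 0.416, 0.245 and 0.0242 with an estimated correlation). In Pfeiffer it gave 0.784, with 0 members called and 1 risen adjusted over the list alone. The plasma cell list was called upward in WSU-DLCL2 (9 rose and 1 fell of 19; adjusted p = 0.045; adjusted p = 0.167 with an estimated correlation). That call ended without replicate A (0.073) or C (0.094) and with the stricter filter (0.080). The list was not called in SU-DHL6 (3 rose and 6 fell; 0.765), Karpas422 (4 and 3; 0.958) or Pfeiffer, where 2 members were called adjusted over the list alone (0.341, but 0.026 as the mean of probe sets). JCHAIN, the joining chain of polymeric antibodies, rose in Karpas422 by 2.59 ± 0.17 while SDC1, the plasma cell surface proteoglycan, changed by −1.70 ± 0.14. In the memory and activated B cell list 4 rose and 5 fell in WSU-DLCL2, 3 and 8 in SU-DHL6 and 3 and 2 in Karpas422 (adjusted p = 0.703, 0.959 and 0.623). CD83 changed by −1.07 ± 0.07 in WSU-DLCL2, and CD86, a T cell costimulator, by 2.37 ± 0.13 in Karpas422. In Pfeiffer this list of 17 genes was called upward (adjusted p = 0.0015; adjusted p = 0.0288 with an estimated correlation). Of its members 0 were called over all genes and 3 adjusted over the list alone, with CD83 at 0.33 ± 0.10 and CD44 at 0.73 ± 0.22. Of the regulators of B cell differentiation, PRDM1 rose in Karpas422 (0.49 ± 0.12). In Pfeiffer it was at 0.59 ± 0.15 and not called (adjusted p = 0.14), but it was called as the mean of its probe sets (0.94, adjusted p = 5.9e-06), in the fit of the 2 groups alone (0.045) and without LCC day 6 replicate B (0.027). BCL6 rose in WSU-DLCL2 (0.46 ± 0.07) and SU-DHL6 (0.56 ± 0.08), in the latter not with the 3'/5' covariate (0.47, adjusted p = 0.13). IRF4 was called in SU-DHL6 (−0.42 ± 0.13), though not with the 3'/5' covariate (−0.40, adjusted p = 0.52), and in WSU-DLCL2 (−0.29 ± 0.15) only without 10xLCC replicate B (−0.55, adjusted p = 4.2e-04).

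**Figure D2:**
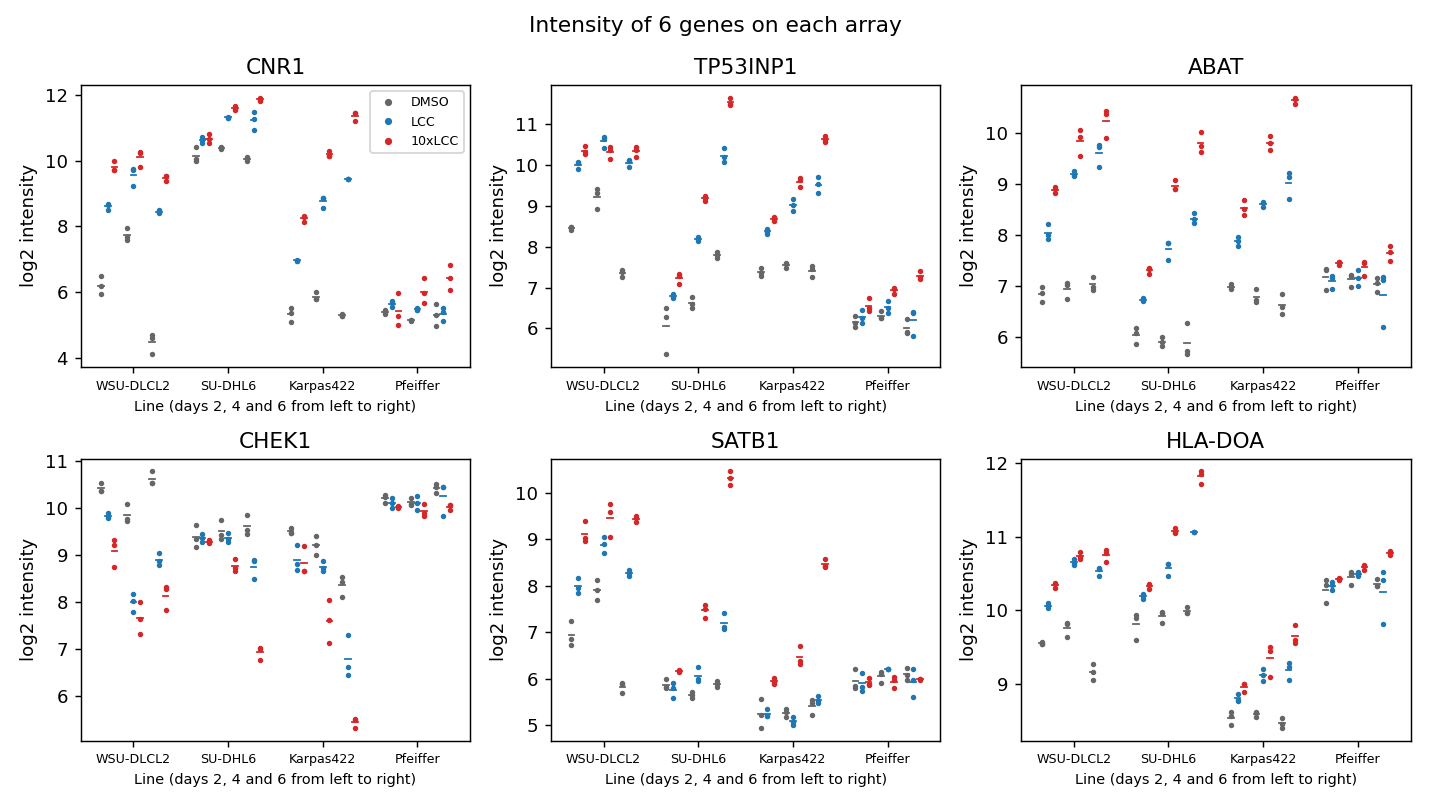
Log2 intensity (vertical axis) of CNR1, TP53INP1, ABAT, CHEK1, SATB1 and HLA-DOA on every array by day, dose and line; points are arrays and short lines are group means (n = 3). CNR1 went from 5.29 to 11.37 between DMSO and 10xLCC at day 6 in Karpas422, and for TP53INP1 and HLA-DOA not all probe sets of the gene moved as the plotted probe set.

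The interferon response divided the lines. Of 30 interferon response genes, which viruses and interferons induce, 29 rose and 0 fell in Karpas422, with RSAD2 at 3.29 ± 0.13, IFI44L at 2.99 ± 0.12 and MX2 at 2.52 ± 0.08. The test gave adjusted p = 9.5e-22, and adjusted p = 0.0014 with an estimated correlation. In WSU-DLCL2 6 rose and 6 fell and in SU-DHL6 6 rose and 1 fell (adjusted p = 0.838 and 0.152). In Pfeiffer 0 were called over all genes and 4 adjusted over the list alone. The list test there gave adjusted p = 2.0e-04 upward, and adjusted p = 0.0306 with an estimated correlation. In Karpas422 27 of the 30 rose at LCC and 29 at 10xLCC at day 4, when the 3'/5' ratio was 0.01 and 0.03. Of 21 NF-kB targets, inflammatory genes, 1 rose and 16 fell in WSU-DLCL2, with TNF at −1.80 ± 0.08, LTA at −1.84 ± 0.09 and ICAM1, an adhesion molecule, at −1.20 ± 0.08. The test gave adjusted p = 1.2e-07, and adjusted p = 0.0194 with an estimated correlation. The NF-kB list was not called in SU-DHL6 (3 rose and 9 fell; adjusted p = 0.187) or in Karpas422 (13 rose and 4 fell; 0.0638, but 0.015 upward as the mean of probe sets). In Pfeiffer it was called upward without a called member (0.0016; adjusted p = 0.459 with an estimated correlation). Within it TNF and LTA fell in SU-DHL6 (−2.03 ± 0.11 and −1.16 ± 0.15), and CCL4, a chemokine, rose in Karpas422 (2.24 ± 0.16).

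Genes of cell death and stress went both ways. Of 23 p53 targets 9 rose and 5 fell in WSU-DLCL2, 10 and 5 in SU-DHL6, 9 and 3 in Karpas422 and 1 and 1 in Pfeiffer. SESN1, a stress-induced inhibitor of growth signalling, rose by 2.91 ± 0.09, 1.56 ± 0.13 and 1.13 ± 0.11 in the Y641 lines. TP53INP1 rose by 2.97 ± 0.11, 3.74 ± 0.17, 3.22 ± 0.10 and 1.28 ± 0.14 in the 4 lines, with 3, 1, 1 and 2 of its 3 probe sets moving that way. The p53 list was called in SU-DHL6 (adjusted p = 0.0120; adjusted p = 0.533 with an estimated correlation) and not in WSU-DLCL2 (0.152), Karpas422 (0.0695, and 0.014 with the 3'/5' covariate) or Pfeiffer (0.205). The glucocorticoid receptor targets were called upward in SU-DHL6 (10 rose and 3 fell of 18; adjusted p = 0.0112; adjusted p = 0.386 with an estimated correlation). They were also called upward in Pfeiffer (0 called, 2 adjusted over the list alone; 1.7e-04; adjusted p = 0.254 with an estimated correlation). They were not called in WSU-DLCL2 (10 and 5; 0.0846) or Karpas422 (6 and 4; 0.399), and DDIT4, an inhibitor of mTOR, was at 1.26 ± 0.09 in WSU-DLCL2 and 3.06 ± 0.09 in SU-DHL6. Of 17 pro-apoptotic genes 4 rose and 8 fell, 4 and 5, 5 and 4, and 1 and 0 in the order WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer (adjusted p = 0.457, 0.647, 0.662 and 0.205). BMF rose by 1.37 ± 0.11, 1.88 ± 0.12 and 1.03 ± 0.22 in the Y641 lines and BID changed by −0.77 ± 0.08, −1.39 ± 0.12 and −1.37 ± 0.16. Of 10 anti-apoptotic genes 0 rose and 4 fell in WSU-DLCL2, among them BIRC5, survivin, at −1.24 ± 0.07 (adjusted p = 0.0161; adjusted p = 0.401 with an estimated correlation). The call ended without replicate B (0.065) and as the mean of probe sets (0.077). That list was not called in SU-DHL6 (2 and 4; 0.529), Karpas422 (4 and 2; 0.457) or Pfeiffer (0 and 0; 0.785). The unfolded protein response was not called in any line (3 rose and 9 fell, 4 and 10, 5 and 9, 0 and 0 of 22; adjusted p = 0.0537, 0.511, 0.526 and 0.618). In WSU-DLCL2 it was called downward under other settings (0.026 without replicate C or as the mean of probe sets, 0.049 with no filter or with the 3'/5' covariate, 0.046 with trend and robust estimates). MANF, a secreted chaperone, changed by −0.95 ± 0.08 there and −1.46 ± 0.14 in Karpas422. Cholesterol synthesis and uptake was called upward in WSU-DLCL2 (9 rose and 1 fell of 19; 0.0178; adjusted p = 0.533 with an estimated correlation). At day 2, in contrast, 2 of its genes rose and 11 fell there at 10xLCC (median −0.34). In DMSO of that line 0 of them rose and 7 fell from day 2 to day 6 (median −0.22). The day 6 rise (median 0.21) thus rests partly on a lower control. The upward call ended without replicate A (0.051) or C (0.13) and as the mean of probe sets (0.063). The list was called downward in Karpas422 (1 rose and 10 fell; 2.5e-04; adjusted p = 0.245 with an estimated correlation) and Pfeiffer (0 and 0; 3.1e-04; adjusted p = 0.533 with an estimated correlation). In SU-DHL6 it was not called (7 and 5; 0.662). TM7SF2, a sterol reductase, rose in WSU-DLCL2 by 1.21 ± 0.07, and EBP and FDPS, enzymes of the pathway, changed by −1.42 ± 0.12 and −1.29 ± 0.11 in Karpas422.

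Among the polycomb genes, PHF19, a PRC2 accessory subunit, changed by −1.21 ± 0.08, −1.64 ± 0.10 and −2.13 ± 0.13 in WSU-DLCL2, SU-DHL6 and Karpas422, and JARID2, another accessory subunit, rose by 0.83 ± 0.10, 1.54 ± 0.11 and 0.80 ± 0.11. EZH2 fell in Karpas422 (−0.51 ± 0.07) and was not called in Pfeiffer (−0.13 ± 0.15). Its calls in WSU-DLCL2 (−0.30 ± 0.10) and SU-DHL6 (−0.26 ± 0.09) ended when arrays were centred (−0.17, adjusted p = 0.063, and −0.16, 0.086). They ended also without WSU-DLCL2 DMSO replicate B (0.14) or 10xLCC replicate B (0.086), and without SU-DHL6 DMSO replicate B (0.083) or C (0.063) or 10xLCC replicate B (0.060) or C (0.17). Of 11 PRC2 subunits 2 rose and 8 fell in WSU-DLCL2 (adjusted p = 0.0452; adjusted p = 0.533 with an estimated correlation). The call ended without replicate B (0.20) and with the stricter filter (0.090). The list was not called in SU-DHL6 (3 and 6; 0.765), Karpas422 (3 and 5; 0.340) or Pfeiffer (0 and 0; 0.363). Of 12 PRC1 subunits 6 rose and 1 fell in SU-DHL6 (adjusted p = 0.0124; adjusted p = 0.401 with an estimated correlation). In WSU-DLCL2 and Karpas422 5 rose and 3 fell (0.511 and 0.340), and in Pfeiffer 0 were called (0.713). CBX7, a reader of the polycomb mark, rose by 1.08 ± 0.11, 2.17 ± 0.10 and 1.97 ± 0.12. Of 6 CDK inhibitors 1 rose and 3 fell in WSU-DLCL2 and in SU-DHL6, 2 and 1 changed in Karpas422 and 0 and 1 in Pfeiffer (adjusted p = 0.136, 0.618, 0.838 and 0.618). CDKN1A rose in WSU-DLCL2 (0.58 ± 0.12) and SU-DHL6 (1.10 ± 0.12), and fell in Pfeiffer (−0.52 ± 0.11, adjusted p = 0.033). The Pfeiffer call ended without DMSO replicate A (adjusted p = 0.26), B (0.11) or C (0.11), without 10xLCC replicate A (0.13), B (0.25) or C (0.083), when arrays were centred (0.086) and with the 3'/5' covariate (0.074). In Karpas422 CDKN1A was at 0.31 ± 0.12 (adjusted p = 0.047), a call that ended without DMSO replicate A (0.057) or C (0.38) and without 10xLCC replicate A (0.10), B (0.061) or C (0.12). It ended also with replicates as blocks (0.056), in the fit of the 2 groups alone (0.099) and with the 3'/5' covariate (0.13). CDKN2A fell in the 3 Y641 lines, at −0.58 ± 0.07, −0.59 ± 0.08 and −0.68 ± 0.10, in SU-DHL6 not with the 3'/5' covariate (−0.49, adjusted p = 0.12), and was at 0.31 ± 0.12 in Pfeiffer (adjusted p = 0.68). There it was called when arrays were centred (0.0039) and without LCC day 6 replicate B (0.025). TXNIP, a regulator of glucose uptake, rose in WSU-DLCL2 (1.41 ± 0.07) and Karpas422 (0.90 ± 0.09). ABAT, which degrades the transmitter GABA, rose by 3.20 ± 0.14, 3.90 ± 0.13 and 4.00 ± 0.12 in the Y641 lines, against 0.61 ± 0.18 (adjusted p = 0.26) in Pfeiffer.

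Lists of other tissues and programmes were not called in any line. Members that rose and fell are given in the order WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer. Homeobox and developmental regulators gave 5 and 2, 6 and 29, 12 and 4, and 0 and 0 (adjusted p = 0.529, 0.241, 0.704 and 0.359). Neuronal genes gave 2 and 2, 1 and 9, 0 and 2, and 0 and 0 (0.765, 0.363, 0.792 and 0.785). MAPK feedback gave 2 and 4, 4 and 5, 5 and 5, and 0 and 0 (0.765, 0.765, 0.838 and 0.958). Integrins and cell adhesion gave 9 and 1, 7 and 6, 4 and 2, and 0 and 0 (0.0639, 0.340, 0.713 and 0.457). In WSU-DLCL2 that list passed without replicate C (0.015) and as the mean of probe sets (0.026). ITGB1, the beta integrin of many matrix receptors, rose there by 1.48 ± 0.10 and in SU-DHL6 by 2.26 ± 0.14. T cell markers gave 2 and 1, 0 and 7, 1 and 3, and 0 and 0 (0.614, 0.0988, 0.363 and 0.475; in SU-DHL6 0.049 with the 3'/5' covariate). Myeloid markers gave 2 and 0, 1 and 5, 1 and 1, and 0 and 0 (0.765, 0.697, 0.882 and 0.489). Epithelial and stromal markers gave 4 and 0, 1 and 1, 2 and 0, and 0 and 0 (0.266, 0.724, 0.958 and 0.205). Single members rose, HOXC6 by 1.21 ± 0.11, the neurofilament gene INA by 2.08 ± 0.08 and the matrix gene DCN by 2.88 ± 0.11 in WSU-DLCL2. In Karpas422 so did the transcription factors SOX9 by 2.13 ± 0.14 and HOXB3 by 2.12 ± 0.19. In all, 11, 10, 9 and 9 lists were called at the preset correlation and 4, 1, 5 and 2 with an estimated correlation. Median, mean and test differed in sign only for lists that were not called. These were MAPK feedback in all 4 lines, memory and activated B cell genes in the Y641 lines, and integrins in SU-DHL6 and Karpas422. In WSU-DLCL2 they included myeloid markers and in SU-DHL6 cholesterol synthesis and uptake. In Karpas422 they included plasma cell, pro-apoptotic, p53 target and homeobox genes, and in Pfeiffer ribosome biogenesis, CDK inhibitors, germinal centre, B cell receptor signalling and neuronal genes. When the labels of the 6 arrays were exchanged, up to 12, 11, 10 and 8 lists were called at the preset correlation and 0 with an estimated correlation. In the Y641 lines the preset counts were thus reached by other splits as well.

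Counts adjusted over the list alone equalled those over all genes in the 3 Y641 lines for mitosis, DNA replication, cholesterol synthesis and uptake, plasma cell, B cell receptor signalling, MHC class II, MAPK feedback and T cell markers. In WSU-DLCL2 the risen and fallen members adjusted over the list alone were otherwise 2 and 9 for PRC2, 1 and 4 for CDK inhibitors, 0 and 19 for ribosome biogenesis, 4 and 6 for memory and activated B cell genes and 8 and 4 for MHC class I. They were 3 and 10 there for the unfolded protein response, 3 and 2 for homeobox genes, 1 and 2 for neuronal genes and 1 and 0 for myeloid markers. In SU-DHL6 they were 0 and 19 for ribosome biogenesis, 11 and 1 for germinal centre genes, 6 and 0 for the interferon response, 3 and 10 for NF-kB targets and 10 and 4 for glucocorticoid receptor targets. For the unfolded protein response they were 6 and 10 in that line, for homeobox genes 6 and 25, for neuronal genes 1 and 4 and for integrins 7 and 7. In Karpas422 they were 6 and 4 for PRC1, 7 and 5 for pro-apoptotic and 5 and 2 for anti-apoptotic genes, 10 and 4 for p53 targets and 6 and 5 for glucocorticoid receptor targets. The unfolded protein response gave 5 and 10, homeobox genes 8 and 3, neuronal genes 0 and 1 and epithelial and stromal markers 1 and 0 in Karpas422. In Pfeiffer the p53 targets gave 3 and 1, CDK inhibitors 1 and 1, MAPK feedback 1 and 0 and epithelial and stromal markers 0 and 1.

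**Figure D3:**
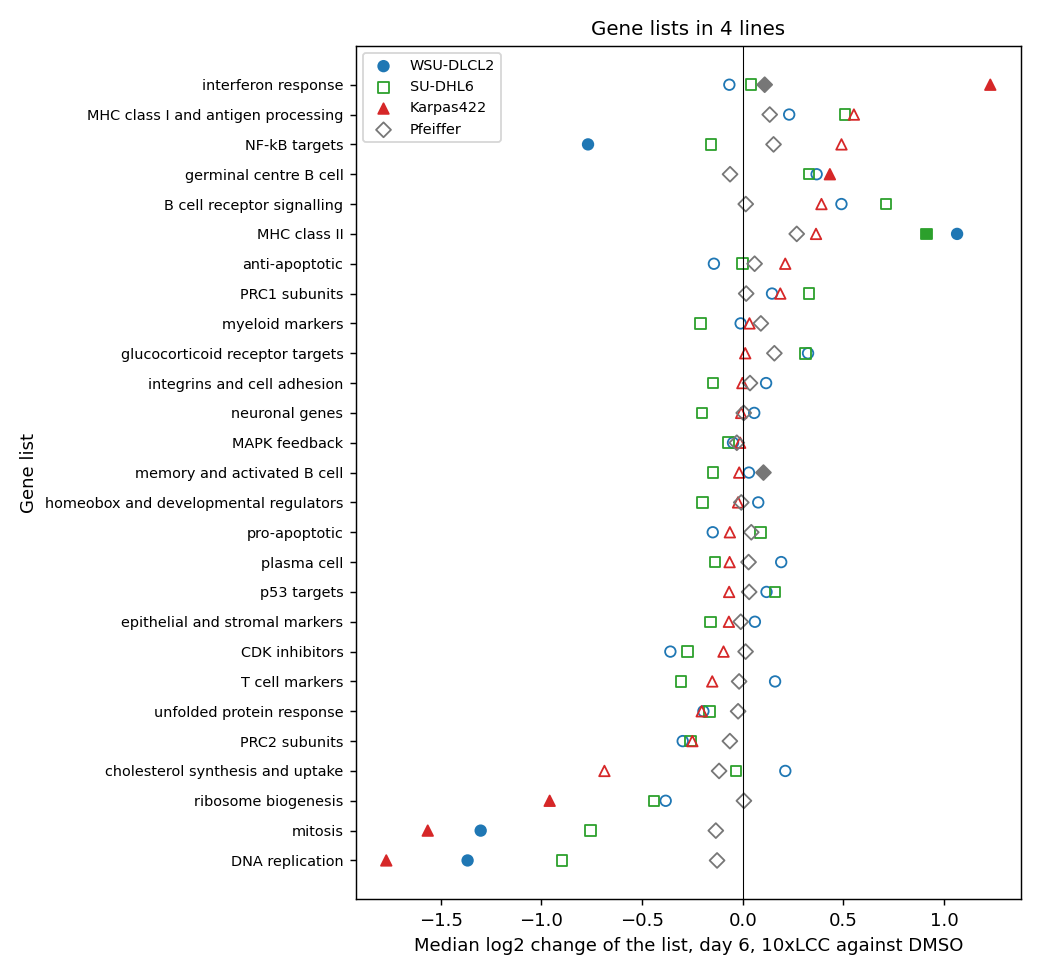
Median log2 change at day 6, 10xLCC against DMSO, of each of the 27 gene lists (vertical axis) in the 4 lines (horizontal axis, log2). Filled markers are lists called with an estimated correlation. DNA replication had a median of −1.37 in WSU-DLCL2, −0.90 in SU-DHL6, −1.77 in Karpas422 and −0.13 in Pfeiffer; centring turned the sign of medians only in lists that were not called.

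The overlap of the lines addressed whether they share a response. TP53INP1 and P4HA2 were among 15 genes that rose in all 4 lines, against 0.190 expected from independent lists. P4HA2 rose by 1.02, 1.96, 4.03 and 1.20 in WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer, with 2 of its 3 probe sets moving that way in each. The mitochondrial gene ND6 fell in all 4 (0.0904 genes expected), by −0.95 ± 0.17 in Pfeiffer. That call ended without Pfeiffer DMSO day 6 replicate A (adjusted p = 0.051) and without 10xLCC day 6 replicate B (0.084) or C (0.083). Across the lines 4 genes rose without replicate A and 1 without replicate C, 0 fell without any 1 replicate, and 139 rose and 31 fell without Pfeiffer LCC day 6 replicate B. Centring gave 153 risen and 55 fallen genes, and the 3'/5' covariate 6 and 1. In the 3 Y641 lines 1204 genes rose together (114.7 expected) and 1606 fell together (187.7 expected), among 18688 genes tested in all lines. Of the 1204, 962 had a positive change in Pfeiffer, with a median of 0.13 there and 0.86 in the Y641 lines, and of the 1606, 1208 had a negative change, with medians of −0.08 and −0.75.

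A direct test asked whether Pfeiffer, without Y641, responded differently from the mean of the 3 Y641 lines. The effect on SATB1 and ABAT was lower in Pfeiffer, with differences of −3.81 ± 0.15 (adjusted p = 1.8e-35) and −3.10 ± 0.17, and so was that on PRKCB (−3.00 ± 0.12), SESN3 (−3.22 ± 0.25) and CNR1 (−3.16 ± 0.18). The difference was positive for TNF (2.43 ± 0.12, adjusted p = 2.4e-30), CHEK1 (2.30 ± 0.19), MCM10 (2.24 ± 0.15) and ELOVL6, a fatty acid elongase (2.15 ± 0.16). For TNF, CHEK1 and MCM10 this came from falls in the Y641 lines and smaller changes in Pfeiffer. In WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer CHEK1 changed by −2.49, −2.69, −2.92 and −0.40 and MCM10 by −2.85, −1.79, −2.75 and −0.22. TNF changed by −1.80, −2.03, −2.63 and 0.27, and ELOVL6 by −1.96, −0.17, −2.32 and 0.67. Limma called 5115 of 19225 genes, with 2834 higher and 2281 lower differences, of which 297 and 487 were at least 2-fold. Centring turned the split to 1955 higher and 4288 lower of 6243. For TMEM200A (−3.30 ± 0.19) the difference from Karpas422 alone was not called (−0.42, adjusted p = 0.21), since its change there was 0.31. Pfeiffer was the only line without the mutation, so this difference is between cell lines.

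The doses were compared at day 6 to ask whether 10xLCC did more than LCC. SATB1 was higher at 10xLCC by 3.13 ± 0.11 in SU-DHL6 and by 2.92 ± 0.12 in Karpas422. So were CXCR4 by 3.02 ± 0.14 in Karpas422 and PRKAR2B, a regulatory subunit of protein kinase A, by 3.33 ± 0.14 in WSU-DLCL2. CHEK1 was lower by −1.82 ± 0.13 in SU-DHL6, and the helicase loader CDT1 and the kinetochore gene SPC25 by −1.56 ± 0.12 and −1.57 ± 0.11 in Karpas422. Of 31 DNA replication genes 28, 30, 30 and 0 were lower at 10xLCC in WSU-DLCL2, SU-DHL6, Karpas422 and Pfeiffer, and of 14 MHC class II genes 5, 11, 5 and 5 were higher and 0, 0, 1 and 0 lower. In Pfeiffer 1 MHC class II gene was higher without LCC replicate B, the array that stood apart from its group, and 1 with the 3'/5' covariate. Limma called 2452 genes (743 higher and 1709 lower) in WSU-DLCL2, 5149 (2204 and 2945) in SU-DHL6, 3435 (1805 and 1630) in Karpas422 and 262 (254 and 8) in Pfeiffer, where RCSD1 led with 1.69 ± 0.13. The WSU-DLCL2 count was 1210 without LCC replicate B and 1188 without 10xLCC replicate B. The Pfeiffer count was 5178, 129 and 3407 without LCC replicates A, B and C and 12 and 23 without 10xLCC replicates B and C. With the 3'/5' covariate 495 genes were called in SU-DHL6 (319 higher and 176 lower) and 17 in Pfeiffer.

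Against DMSO, LCC at day 6 called 5238 genes (3130 risen and 2108 fallen) in WSU-DLCL2, 3377 (1924 and 1453) in SU-DHL6 and 4965 (2208 and 2757) in Karpas422. In Pfeiffer it called 0, and limma gave 2365 genes an unadjusted p under 0.05. At day 4 LCC called 5437, 1590, 1675 and 0 genes (645 in Pfeiffer at an unadjusted p under 0.05) and 10xLCC 6322, 3771, 4912 and 13. At day 2 LCC called 1327, 890, 505 and 0 (543 at an unadjusted p under 0.05 in Pfeiffer) and 10xLCC 4794, 1633, 1245 and 1. At that threshold chance alone gives more genes than the 645 and 543 of days 4 and 2, and fewer than the 2365 of day 6. The Pfeiffer LCC day 6 group held replicate B, which lay 0.723 from its group, and the median change of all genes there was −0.08. The 2365 can therefore not be read as an effect of LCC. The 645 and 543 rest on a pooled spread that included this array, so they do not show an absence of change. Several of these counts moved by more than 1.5 times without single arrays. Without DMSO day 2 replicates A, B and C the SU-DHL6 day 2 counts were 357, 1821 and 3269 at LCC and 975, 2673 and 3891 at 10xLCC. Without LCC day 2 replicates A, B and C the LCC count was 533, 475 and 481, without 10xLCC day 2 replicate B the 10xLCC count was 1049, and without LCC day 6 replicate C the LCC day 6 count was 2016. In WSU-DLCL2 the LCC day 2 count was 794 and 828 without DMSO replicates A and B and 879, 845 and 852 without LCC replicates A, B and C. In Karpas422 it was 278, 255 and 231 without DMSO replicates A, B and C and 246 and 188 without LCC replicates A and C. There the 10xLCC day 2 count was 791 and 800 without DMSO replicates A and B and 807 and 770 without 10xLCC replicates B and C, and the LCC day 4 count was 1071 without LCC replicate A. In Pfeiffer the 10xLCC day 4 count was 4 and 6 without DMSO replicates B and C and 4 without any 1 of the 10xLCC arrays, but 664 (392 risen and 272 fallen) without LCC day 6 replicate B. With the 3'/5' covariate the LCC day 6 count was 1912 in SU-DHL6 and 2892 in Karpas422, where the ratio was 2.37 at LCC and 1.25 in DMSO, and the 10xLCC day 2 count in WSU-DLCL2, where the ratio was 0.17 at 10xLCC and −0.07 in DMSO, was 2765. For 10xLCC, DNA replication genes that fell numbered 30, 31 and 31 at days 2, 4 and 6 in WSU-DLCL2, 0, 25 and 29 in SU-DHL6 and 9, 29 and 31 in Karpas422. With the covariate they numbered 29, 31 and 31, then 0, 25 and 18, and 11, 31 and 31. MHC class II genes that rose numbered 7, 13 and 14 in WSU-DLCL2, 6, 12 and 14 in SU-DHL6 and 3, 7 and 7 in Karpas422, and with the covariate 6, 12 and 14, then 6, 12 and 10, and 5, 9 and 11.

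Whether the 10xLCC effect grew was tested as the effect at day 6 minus that at day 2. In SU-DHL6 FCRL4, SATB1 and CCR7 gained 5.21 ± 0.21, 4.15 ± 0.15 and 3.90 ± 0.29, and CHEK1 and DLGAP5 changed by −2.59 ± 0.19 and −2.58 ± 0.24. In Karpas422 CXCR4, ZNF595 and PMAIP1 gained 4.19 ± 0.20, 3.48 ± 0.33 and 3.45 ± 0.21, and LMNB1, a nuclear lamina gene, and MCM4 changed by −2.36 ± 0.37 and −2.33 ± 0.24. In WSU-DLCL2 the effect on EGR1, an immediate early transcription factor, changed sign, from −2.33 ± 0.18 at day 2 to 1.86 ± 0.18 at day 6. Part of this difference of 4.19 ± 0.25 was a fall of EGR1 in DMSO between these days. The effect on RAPH1 changed by −2.64 ± 0.24. Limma called 2611 genes (1405 higher and 1206 lower) in WSU-DLCL2, 5932 (1940 and 3992) in SU-DHL6, 3757 (1826 and 1931) in Karpas422 and 0 in Pfeiffer (445 at an unadjusted p under 0.05). Chance alone gives more than 445 at that threshold, but Pfeiffer's pooled spread included LCC day 6 replicate B. The count therefore does not show that the effect stayed the same in Pfeiffer. With the 3'/5' covariate 506 genes were called in SU-DHL6 (254 and 252), and the call of MAD2L1 (−2.50 ± 0.27) ended (−1.24, adjusted p = 0.079).

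**Figure D4:**
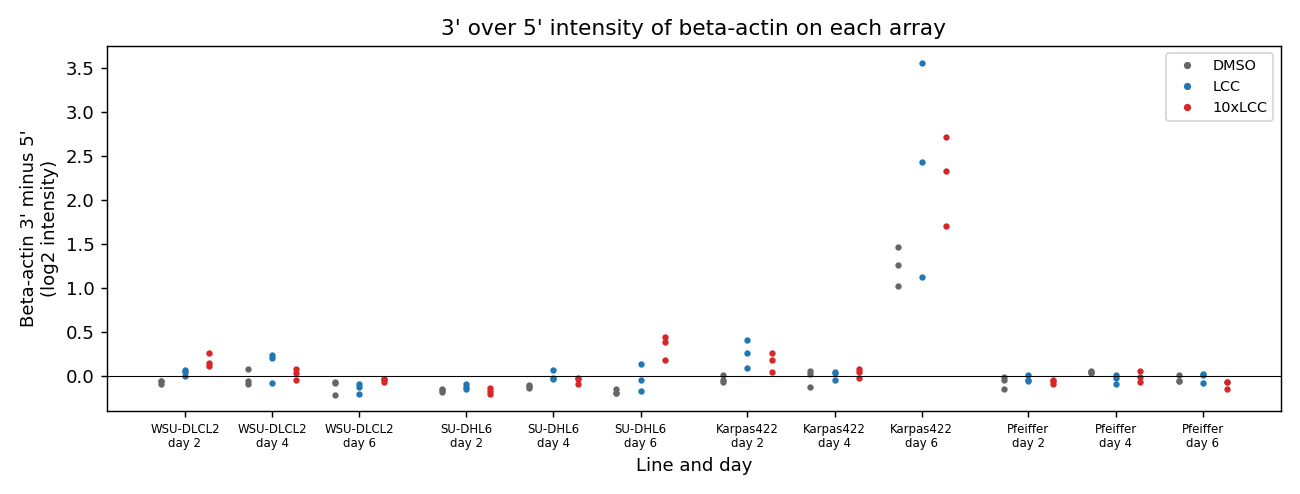
The log2 ratio of the 3' to the 5' beta-actin control (vertical axis) on every array by day and dose in the 4 lines; points are arrays (n = 3 per group). The group means were 1.25, 2.37 and 2.25 in Karpas422 DMSO, LCC and 10xLCC at day 6, and −0.18, −0.03 and 0.34 in SU-DHL6.

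Cells kept in DMSO also changed with time, as day 6 against day 2 shows. In SU-DHL6 FAS, a death receptor, and BCL2A1 rose by 2.65 ± 0.22 and 2.63 ± 0.17, and SESN1 by 2.04 ± 0.13. In WSU-DLCL2 LAMP3, a lysosomal protein, and BCL2A1 rose by 1.93 ± 0.14 and 1.43 ± 0.15, and EGR1 and CTH, an enzyme of cysteine synthesis, changed by −2.17 ± 0.18 and −2.02 ± 0.11. In Karpas422, where the 3'/5' ratio went from −0.03 at day 2 to 1.25 at day 6, CYTOR and LTB4R rose by 2.08 ± 0.18 and 1.88 ± 0.16. ARPC5, of the actin nucleation complex, and SUCLG2, of the citric acid cycle, changed by −3.33 ± 0.13 and −3.11 ± 0.19. Limma called 2277 genes (687 risen and 1590 fallen) in WSU-DLCL2, 670 (560 and 110) in SU-DHL6, 5925 (2849 and 3076) in Karpas422 and 1 in Pfeiffer, MAGEA6, a cancer-testis antigen, at 0.87 ± 0.11. The SU-DHL6 count was 1090 and 2476 without DMSO day 2 replicates B and C and 166 without DMSO day 6 replicate A. Without LCC day 6 replicate B the Pfeiffer count was 698 (622 risen and 76 fallen).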

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

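The tests of degraded RNA as part of the cause in SU-DHL6 and Karpas422 and both tests of the few calls in Pfeiffer were chosen only after the results were seen. Results were taken up here when a test of the difference itself between cell lines or between days called them, or when they came from probe sets that the named comparisons did not use, and contrasts that were not called are given beside them.

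The effect of 10xLCC at day 6 differed between Pfeiffer and the mean of the Y641 lines for 5115 genes. Of 100 drawn splits of the arrays within lines only 1, the real one, gave as many (highest other 3593). The splits exchanged treatment labels within each line and never exchanged lines. They test for a treatment effect in any line, so they do not tell whether chance gave the difference between lines. The cell cycle gene differences, Pfeiffer minus the Y641 mean in log2, were 2.30 for CHEK1, 2.24 for MCM10, 1.86 for ORC1, 1.84 for TRIP13, 1.81 for CDC6 and 1.74 for SPC25. TNF differed by 2.43 and ELOVL6 by 2.15. The lower values were −3.81 for SATB1, −3.30 for TMEM200A, −3.22 for SESN3, −3.16 for CNR1, −3.10 for ABAT, −3.00 for PRKCB, −2.85 for ZMAT1 and −2.84 for SETBP1. For TMEM200A the difference of Pfeiffer from Karpas422 alone was not called (−0.42, adjusted p = 0.21).

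Lists differed between lines as well, tested on the difference with an estimated correlation. Against the Y641 lines, Pfeiffer's median list difference was 1.22 for DNA replication (adjusted p = 0.0014), 1.08 for mitosis, −0.54 for MHC class II, −0.46 for B cell receptor signalling and −0.41 for the interferon response. The last came from Karpas422, whose interferon median was 1.23, while Pfeiffer's, 0.11, lay above those of WSU-DLCL2 (−0.07) and SU-DHL6 (0.04). For MHC class II the medians were 1.065 in WSU-DLCL2, 0.913 in SU-DHL6, 0.364 in Karpas422 and 0.268 in Pfeiffer. Karpas422 thus lay nearer to Pfeiffer than to the other Y641 lines. Against the other Y641 lines the interferon response differed by 1.11 in Karpas422 (adjusted p = 1.2e-09), −0.89 in WSU-DLCL2 and −0.60 in SU-DHL6, and NF-kB targets by 0.83 in Karpas422 and −0.66 in WSU-DLCL2. Each line was set against the mean of the other Y641 lines, so these contrasts are not independent. The negative interferon values came from Karpas422 in that mean, since the medians of WSU-DLCL2 and SU-DHL6 themselves were −0.07 and 0.04. For NF-kB targets the medians were −0.77 in WSU-DLCL2, −0.16 in SU-DHL6 and 0.49 in Karpas422.

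Between day 2 and day 6 the 10xLCC effect differed for 2611 genes in WSU-DLCL2, 5932 in SU-DHL6 and 3757 in Karpas422. In WSU-DLCL2 the difference was 4.19 for EGR1, part of it a fall in DMSO between these days. The other differences there were 3.52 for TMEM200A, 3.34 for LOC613266, −2.64 for RAPH1, −2.29 for LOC145474 and −2.20 for SSUH2. In SU-DHL6 they were 5.21 for FCRL4, 4.15 for SATB1, 3.90 for CCR7, −2.59 for CHEK1, −2.58 for DLGAP5 and −2.50 for MAD2L1, and in Karpas422 4.19 for CXCR4, 3.48 for ZNF595, 3.45 for PMAIP1, −2.48 for SMG1P5, −2.36 for LMNB1 and −2.33 for MCM4. Of 100 drawn splits of the arrays within days 14 gave as many genes in WSU-DLCL2 (highest 7353) and 9 in Karpas422 (5682), and 4 in SU-DHL6 (7152). Most of the other splits that gave as many kept the treated day 6 arrays together, 12 of 13 in WSU-DLCL2, 3 of 3 in SU-DHL6 and 8 of 8 in Karpas422. Those splits still hold the day 6 effect, and 12, 5 and 8 of them were drawn, so the shares of 100 do not tell whether chance gave these counts. With the treated day 6 arrays split up, the highest counts were 2632 in WSU-DLCL2, 322 in SU-DHL6 and 3 in Karpas422. In Pfeiffer, with 0 genes called by limma, 100 of 100 splits gave as many (highest 38). There 445 genes had an unadjusted p under 0.05, fewer than chance gives, from a pooled spread that included LCC day 6 replicate B.

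Probe sets that stand for no single named gene were tested in the same way at day 6, 10xLCC against DMSO. Those called numbered 1926 of 11804 in WSU-DLCL2, 4800 of 11880 in SU-DHL6, 2731 of 11867 in Karpas422 and 7 of 11761 in Pfeiffer.

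Degraded RNA was weighed for the large day 6 counts of SU-DHL6 and Karpas422, where the 3'/5' ratio was higher in treated arrays. As the whole cause it was excluded in Karpas422. There the day 4 change, when the ratios were near 0, had the sign of the day 6 change for 91.64% of the 7093 genes called (1668 of 1681 changed at least 2-fold). In SU-DHL6 this share was 77.83% of the 8785 genes called (1550 of 1621), above the bound of 75% set beforehand. But the ratio was higher in treated SU-DHL6 arrays at day 4 too, −0.05 ± 0.035 against −0.12 ± 0.018 in DMSO (SD, n = 3). A smaller difference of the same kind could give the same signs, so the share cannot exclude degraded RNA as the whole cause in SU-DHL6. In WSU-DLCL2, where the mean day 6 ratios were −0.12 in DMSO and −0.05 at 10xLCC, that share was 83.36%. As part of the cause it stays open in SU-DHL6: with the ratio as a covariate 78.93% of the change was left and 1647 of the calls held, while the SE grew 2.21-fold, from 0.113 to 0.249, so for that part treatment and RNA quality cannot be told apart. In Karpas422, where the SE grew only 1.02-fold, 90.34% was left (bootstrap SD 0.716 percentage points), and 5761 of 7093 calls held and 7078 kept their sign. The share did not pass the bound of 90% by 2 SD, so a part stays open. This SD came from draws of genes, not of arrays, so it leaves out the spread between arrays.

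The few calls in Pfeiffer had a technical candidate in LCC day 6 replicate B, which may have widened the pooled spread. Without it 450 genes were called, above 42 and below the 6808 genes of WSU-DLCL2, the lowest count of a Y641 line, so that array was not the whole cause. A wider spread with changes as large as elsewhere was set against the slope of Pfeiffer's changes on the Y641 mean. Over the 2810 genes called the same way in all Y641 lines it was 0.1151, so these genes changed less in Pfeiffer. They were chosen by their Y641 changes, which pulls the slope down, and for other genes the question stays open. The absence of the Y641 mutation stays open and untested, since Pfeiffer was the only line without it, and so does the concentration that LCC stood for. Other EZH2 mutations in these lines were not examined.

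The interferon response in Karpas422 was set against degraded RNA, which could raise some probe sets. It was excluded, because 29 of 30 genes had already risen at day 4, when the 3'/5' ratio was 0.03. A response of this line to EPZ6438 remains a hypothesis. No test of infection or secreted interferon was made.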

How the results depend on the processing

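The array weights, the 3'/5' covariate and the fit without Pfeiffer LCC day 6 replicate B were chosen only after the results were seen. For 627 named gene values, 9295 results under alternatives had the same direction and side of the threshold, 148 passed it newly, 265 no longer did and 2 reversed; for the 108 list tests the numbers were 1164, 13, 38 and 0. The reversals were COL1A1 in SU-DHL6 (0.062) and CDKN2B in Karpas422 (0.38), each as the mean of probe sets, which replaces the brightest by several. Causes were otherwise not tested. Signal over background limits dim genes, and 3 arrays per group limit the rest.

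Array weights, whose estimate converged only in WSU-DLCL2 (lowest weights elsewhere 0.068 to 1.8e-08), gave in WSU-DLCL2 4828 genes for LCC day 2, 4079 for the change of the effect and 4855 for DMSO over time. In SU-DHL6 they gave 8111 and 9327 for LCC and 10xLCC day 2, 3161 for LCC day 4 and 5484 for DMSO. In Karpas422 they gave 3588 and 4117 for day 2, 4330 for LCC day 4, 10610 for LCC day 6, 8427 for 10xLCC against LCC and 5727 for the change of the effect. In Pfeiffer they gave 20 and 52 for day 2, 1069 and 1016 for 10xLCC days 4 and 6, 51 for 10xLCC against LCC, 144 for the change of the effect and 1944 for DMSO, and 282 risen and 70 fallen genes shared by all lines. The covariate gave 2765 for WSU-DLCL2 10xLCC day 2, 1912 (1405 risen and 507 fallen), 1675, 495 and 506 for SU-DHL6 LCC day 6, 10xLCC day 6, 10xLCC against LCC and the change of the effect, and 2892 (1580 and 1312) for Karpas422 LCC day 6. It gave 17 for Pfeiffer 10xLCC against LCC and 6 risen in all lines. Without Pfeiffer LCC day 6 replicate B the line gave 2, 664 and 450 for 10xLCC days 2, 4 and 6, 10 for the change of the effect and 698 for DMSO, and 139 and 31 were shared. Centring gave 458 in Pfeiffer at 10xLCC day 6 and 153 and 55 shared. The fit of the 2 groups alone gave 90 there, the replicate block 6 at 10xLCC day 4, and trend and robust estimates 2 for DMSO. On average the letters did not pair arrays: the mean correlation of the same letter's residuals across groups was −0.0185, −0.00727, 0.0206 and −0.0172. Single correlations ran from −0.537 in WSU-DLCL2 to 0.566 in Karpas422, so the means leave open a pairing between some groups. With an estimated correlation 4, 1, 5 and 2 lists were called.

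Leaving out single arrays of the groups compared gave these lowest and highest counts. In WSU-DLCL2 LCC gave 794 to 909 at day 2, 4599 to 5317 at day 4 and 4502 to 4880 at day 6; 10xLCC gave 3669 to 4371, 5641 to 6069 and 6084 to 6862; 10xLCC against LCC gave 1188 to 2906, the change of the effect 2135 to 2651 and DMSO 1538 to 1723. In SU-DHL6, in the same order, the ranges were 357 to 3269, 1075 to 1684, 2016 to 3220, 975 to 3891, 2943 to 3363, 7507 to 8215, 3911 to 5208, 5221 to 6584 and 166 to 2476. In Karpas422 they were 188 to 676, 1071 to 1275, 3675 to 6050, 770 to 1203, 4105 to 5197, 6320 to 6877, 2553 to 4309, 3174 to 3736 and 5012 to 5449. In Pfeiffer they were 0, 0 and 0 for LCC, 0 to 1, 4 to 10 and 12 to 33 for 10xLCC, 12 to 5178, 0 and 1. The difference of Pfeiffer from the Y641 lines gave 4528 to 5163. Leaving out replicate A, B or C of every group gave 1 to 10 risen and 0 fallen genes shared by all lines, and 9 to 11, 9 to 10, 9 and 9 lists. Counts moved by over 1.5 times on WSU-DLCL2 LCC day 2 without DMSO A (794) or B (828) or LCC A (879), B (845) or C (852), and on 10xLCC against LCC without LCC B (1210) or 10xLCC B (1188). For SU-DHL6 LCC day 2 they did without DMSO A (357), B (1821) or C (3269) or LCC A (533), B (475) or C (481), and for 10xLCC day 2 without DMSO A (975), B (2673) or C (3891) or 10xLCC B (1049). There they also did for LCC day 6 without LCC C (2016) and for DMSO over time without day 2 B (1090) or C (2476) or day 6 A (166). For Karpas422 LCC day 2 they did without DMSO A (278), B (255) or C (231) or LCC A (246) or C (188), for 10xLCC day 2 without DMSO A (791) or B (800) or 10xLCC B (807) or C (770), and for LCC day 4 without LCC A (1071). For Pfeiffer 10xLCC day 2 they did without DMSO B or C or any 10xLCC array (0 each), for 10xLCC day 4 without DMSO B (4) or C (6) or any 10xLCC array (4), and for 10xLCC day 6 without DMSO A (12), B (20) or C (27) or 10xLCC B (16) or C (21). For 10xLCC against LCC they did without LCC A (5178), B (129) or C (3407) or 10xLCC B (12) or C (23). The shared risen genes moved without replicate A (4) or C (1) and the fallen without any (0).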

Other observations

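The test of DMSO over the early days was chosen only after the results were seen. WSU-DLCL2 kept in DMSO changed between day 2 and day 4, with 2694 genes called by limma, against 22 in SU-DHL6, 22 in Karpas422 and 1 in Pfeiffer. Of the 1606 genes that fell with 10xLCC at day 6 in all 3 Y641 lines, 764 were lower and 4 higher in WSU-DLCL2 DMSO at day 4, with a median of −0.27. Of the 1204 that rose, 110 were higher and 84 lower. Each treated group was compared with DMSO of its own day, and the day 4 comparison of WSU-DLCL2 is therefore with cells in which many of the genes that fell with treatment were themselves lower than at day 2.

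The labels of the 6 arrays of each comparison of groups were exchanged in every possible way, 10 splits each, which are too few for a share under 0.05. In WSU-DLCL2 the real split gave the most genes in 1 of 10, with the highest other at 34 for 10xLCC day 4 (real 6322), 1 for 10xLCC against LCC (2452) and 0 for the other comparisons. In SU-DHL6 it was also 1 of 10 throughout, with 2 for LCC day 2 (890), 1 for 10xLCC day 2 (1633), 1 for LCC day 6 (3377), 112 for 10xLCC against LCC (5149), 407 for DMSO over time (670) and 0 elsewhere. In Karpas422, again 1 of 10, it was 1 for LCC day 4 (1675), 1161 for LCC day 6 (4965), 1440 for 10xLCC against LCC (3435) and 0 elsewhere. In Pfeiffer the 3 LCC comparisons with 0 genes called were matched by 10 of 10, and the others gave 1 of 10, with 1 for 10xLCC against LCC (262) and 0 elsewhere.

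Exchanging treatment labels within the lines gave no gene that rose or fell in all 4 (highest 0, and 1 of 100 splits as large for each, the real one), against 15 and 1 genes with the real labels. Since exchanged labels called 0 genes within each line at day 6 with 10xLCC, their overlap was bound to be 0, so these splits do not test the sharing between lines. For lists, again with too few splits for a share under 0.05, the real and highest other counts at the preset correlation were 11 and 12 in WSU-DLCL2 (4 of 10 as large), 10 and 11 in SU-DHL6 (3 of 10), 9 and 10 in Karpas422 (6 of 10) and 9 and 8 in Pfeiffer (1 of 10). With an estimated correlation they were 4, 1, 5 and 2, each with 0 as the highest other.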
